A study of Mus musculus with 18 samples.

How the data were processed

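Polyadenylated RNA was sequenced from 18 libraries of cultured mouse cells, 9 of the liver cancer line Hepa1-6 and 9 of the melanoma line B16. In each line 3 libraries came from cells with a control guide RNA (sgCtrl) and 3 from cells with each of 2 guide RNAs against Ncor1 (sgNcor1-1 and sgNcor1-2), which makes 6 groups of 3 libraries. Per the labels' protocols, RNA was purified on columns, libraries were made with a VAHTS mRNA-seq kit and reads came from a NovaSeq instrument. Nothing in the labels says that the kit marks strand, so reads of a gene and of an overlapping or antisense partner cannot be told apart.

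Per the submitters' processing notes, reads were checked with FastQC 0.12.1, trimmed with Trim Galore 0.6.7, aligned to the mouse genome build mm10 with Bowtie2 2.2.5 and counted with RSEM 1.2.8. The gene annotation behind the counts is not given in the sources used here. The values used here are the expected counts per gene that the authors deposited, 1 table per cell line, with 32015 gene symbols in each. RSEM shares reads that align to several genes among them, so 7.87% of the values in the Hepa1-6 table and 7.19% in the B16 table were not whole numbers. Genes with near-identical copies are therefore less certain than single-copy genes. All values were rounded to whole numbers before any test. Of the gene symbols, 31678 (98.9%) had a single position in the reference gene table of the same genome build, from which chromosomes and coordinates were taken.

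Total counts per library lay between 17689350 and 30819710 in Hepa1-6 and between 15663985 and 25263758 in B16. No pair of libraries within a line was alike enough to be 1 library counted under 2 names. The lowest chi-square per degree of freedom over genes was 11.57 in Hepa1-6 and 6.61 in B16, both for a library of each Ncor1 guide. Nothing says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Limits set from a count of 0 cover counting error only.

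Levels are in CPM, counts scaled to the same total per library, with library sizes scaled by the trimmed mean of M values (TMM), given as mean ± SD over 3 libraries. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with its own filter on low counts, TMM factors, a robust spread estimate and 1 mean per group. All 9 libraries of a line shared 1 estimate of the spread. Knockout against control was the mean of both Ncor1 guides minus sgCtrl on the log2 scale, and each guide was also tested alone and against the other guide. The difference of the knockout effect between lines was a contrast in a joint fit of all 18 libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and adjusted values under 0.05 were called. The fit tested 12458 genes in Hepa1-6 and 12347 in B16, of which 10878 were tested in both. Log2 fold changes are given with standard errors (SE).

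The study's design, the tests, the alternatives not named below as later additions and 34 gene lists were fixed before the data were examined. The lists covered DNA repair, the NCoR complex, antigen presentation and innate immunity, nuclear receptor targets, lipid synthesis, cell cycle and stress programmes. They also covered identity markers of both lines, markers of other cell types, and signs of handling and RNA quality. The lists held 982 entries, of which 44 were renamed through synonyms and 0 were not found. Each list with at least 5 measured members was tested with the camera function of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of a line. The same test with an estimated correlation, and the fry test, were alternatives. Adjusted p-values of genes in the text come from edgeR and those of lists from camera unless another tool is named.

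Genes named in the text followed a fixed rule. It took Ncor1, and up to 10 rises and 10 falls among genes called with each guide and in the mean of both. These needed a mean of at least 5 CPM, no overlap of knockout and control libraries, and a gene name rather than a model number. It also took mismatch repair genes whatever their p, and up to 4 members of each list described, those with the smallest p. Between the guides and between the lines it took 3 genes each way under the same filters. Other genes are named as chosen after their values were seen.

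Libraries carry replicate numbers 1 to 3 in every group, and whether these pair libraries was checked by correlating deviations from the group means. In B16 all 9 correlations between libraries of the same number lay between 0.50 and 0.74, so the numbers were taken to pair the libraries. A fit with the number as a block is given there where it changes a call. In Hepa1-6 the pairs of sgCtrl and sgNcor1-2 reached 0.59, 0.19 and 0.34 and those of both Ncor1 guides 0.91, 0.67 and 0.75, but the pair of sgCtrl and sgNcor1-1 numbered 2 reached only 0.05. The blocked fit in Hepa1-6 is therefore set beside the comparisons of sgNcor1-2 alone. For knockout against control there it is given as an alternative only. The labels do not say what a number stands for.

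Alternatives were DESeq2 1.42.0, limma-voom, size factors of the RLE method, no filter on low counts, a filter at 1 CPM, a minimum log2 fold change of 1, the replicate block, 1 pooled knockout group, fits of the 6 libraries compared, and each library left out in turn. The fits that leave out all libraries of 1 number, the blocked fits without some libraries, the blocked fit with DESeq2, and the list tests with the block were added after the data were seen. The tests were tried on simulated counts with 100 genes changed by each of 2 known amounts, which kept the replicate-number effects estimated by the blocked fit. The edgeR test recovered 23% of changes of 1 and 86% of changes of 2 on the log2 scale in a simulation of Hepa1-6 knockout against control over 12304 genes. In a simulation of the same comparison in B16 over 12238 genes it recovered 11% and 84%. On the same counts edgeR with the replicate block recovered 92% of changes of 1 in Hepa1-6 and 85% in B16. Of its calls, 18 of 213 in Hepa1-6 and 10 of 197 in B16 were unchanged genes. The counts were drawn from the blocked fit, with its spread and number effects shared by all groups, so the block was favoured by design. In Hepa1-6 the numbers were not taken to pair knockout with control libraries, so the rates there rest on a setting that may not hold. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.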

Results

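Gene expression was measured by RNA sequencing in 2 mouse tumour cell lines, the liver cancer line Hepa1-6 and the melanoma line B16, after CRISPR targeting of Ncor1. NCOR1 is a corepressor that holds histone deacetylase 3 at target genes of nuclear receptors. The series title asks whether NCOR1 facilitates DNA mismatch repair and whether its loss sensitises tumours to immune checkpoint blockade. Each line had 3 libraries with a control guide (sgCtrl), 3 with the guide sgNcor1-1 and 3 with the guide sgNcor1-2. A library is named below by its guide and replicate number, such as sgCtrl 1.

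Libraries numbered 1, 2 and 3 held 18670720, 20230156 and 20202356 counts in Hepa1-6 sgCtrl, 28798755, 17689350 and 27291706 in sgNcor1-1, and 30819710, 24438421 and 20356345 in sgNcor1-2. In B16 they held 20554668, 16374231 and 20952344 counts in sgCtrl, 15663985, 16409653 and 17367951 in sgNcor1-1, and 25263758, 17835715 and 17299276 in sgNcor1-2. Between 13984 and 15976 genes had at least 1 count per library, and the 10 most abundant genes took 4.5% to 9.0% of the counts. In Hepa1-6 the 3 libraries numbered 1 stood apart, with values of -27.4 (sgCtrl), -71.9 (sgNcor1-1) and -70.1 (sgNcor1-2) on the first principal component, which held 53.3% of the variance. The other 6 libraries lay between 14.2 and 37.2. In B16 the library sgNcor1-1 1 stood apart at -96.5 on a first component with 48.6% of the variance. It had the fewest detected genes (13984) and a TMM factor of 0.792, against 0.978 to 1.091 in the other 8.

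Ncor1 RNA was lower in the Hepa1-6 knockout libraries but did not pass the main test, and it lay at the control level in B16. Ncor1 lies on chromosome 11 from 62315663 to 62457414. In Hepa1-6 it stood at 250.5 ± 25.1 CPM with sgCtrl, 168.2 ± 34.2 with sgNcor1-1 and 158.3 ± 24.3 with sgNcor1-2 (SD, n = 3 each). The log2 fold change was -0.62 (SE 0.17, adjusted p = 0.223, edgeR), and the highest knockout library (196.9 CPM) lay below the lowest control (221.6 CPM). With the replicate block edgeR called Ncor1 in Hepa1-6, though the numbers were not taken to pair these libraries. In B16 the levels were 310.4 ± 27.1, 300.6 ± 64.3 and 296.7 ± 58.1 CPM, with a log2 fold change of -0.06 (SE 0.19, adjusted p = 1). The difference between the lines was -0.55 on the log2 scale (adjusted p = 0.72). A small insertion or deletion in an exon need not lower the RNA of a gene, so the RNA level in B16 is no check of the knockout. The other measured members of the NCoR and SMRT complex list did not pass the test in either line (list adjusted p = 0.473 in Hepa1-6 and 0.438 in B16, camera). Hdac3, the deacetylase of the complex, had log2 fold changes of 0.27 (SE 0.14) in Hepa1-6 and -0.10 (SE 0.16) in B16.

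**Figure D1:**
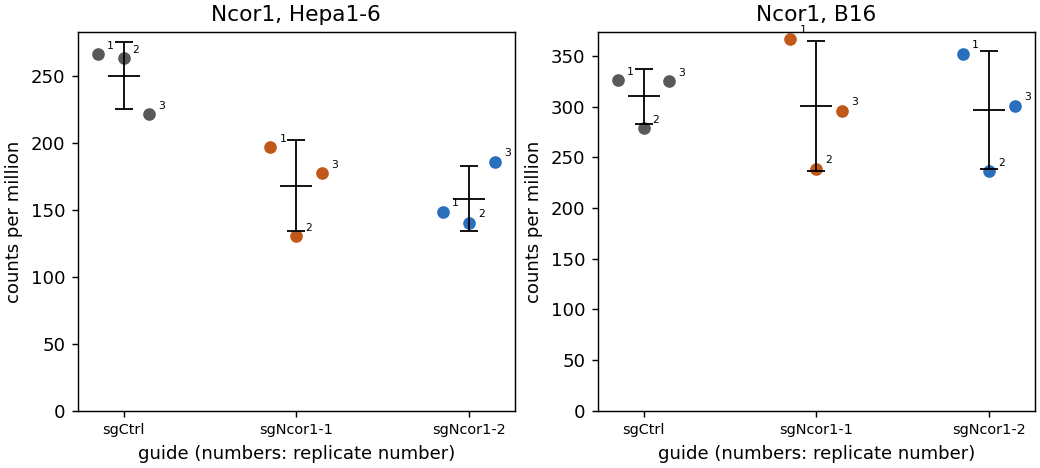
Ncor1 level in each of the 18 libraries in CPM on an axis that starts at 0, by cell line and guide, with points numbered by replicate and bars for mean ± SD (n = 3). Hepa1-6 knockout libraries lie between 130.4 and 196.9 CPM and controls between 221.6 and 266.3, while the groups overlap in B16.

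In Hepa1-6, knockout against control asked which genes change when Ncor1 is targeted in liver cancer cells. Adcy8, an adenylyl cyclase that makes cyclic AMP, rose from 0.2023 ± 0.104 CPM to 9.115 ± 1.7 with sgNcor1-1 and 9.42 ± 0.578 with sgNcor1-2 (SD, n = 3 each). Pcx, the mitochondrial pyruvate carboxylase that makes oxaloacetate, rose from 26.74 ± 12.6 CPM to 344.4 ± 29 and 360.9 ± 54.7. Frmd8, a FERM domain protein of the iRhom and ADAM17 shedding complex, fell from 51.65 ± 4.91 CPM to 2.463 ± 0.972 and 2.029 ± 1.05. These 3 genes met the rule for naming large changes.

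The log2 fold change was 5.48 for Adcy8 (SE 0.39, adjusted p = 0.00131), on chromosome 15 from 64699035 to 64922296. It was 3.72 for Pcx (SE 0.32, adjusted p = 0.00177), on chromosome 19 from 4510472 to 4621752. It was -4.54 for Frmd8 (SE 0.35, adjusted p = 0.00163), on chromosome 19 from 5850974 to 5875269. Beside Frmd8 lies Neat1, a long noncoding RNA that builds paraspeckles, from 5824708 to 5845480. Neat1, chosen after its values were seen, had 37.69, 227.8 and 269.9 CPM in the controls and 0 counts in all 6 knockout libraries. Against a floor of 3 counts per library (0.171 CPM) it was at least 1040-fold lower (adjusted p = 0.0179), though neither guide alone passed the test (adjusted p = 0.0999 and 0.0813). With the replicate block, sgNcor1-2 alone passed (adjusted p = 0.000159). The Neat1 call was lost without sgCtrl 2 (adjusted p = 0.127), sgCtrl 3 (0.106) or sgNcor1-1 2 (0.0575).

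In all, 25 genes were called in Hepa1-6, 7 higher and 18 lower (edgeR). Those called with each guide also included Enpp2 (autotaxin, which makes lysophosphatidic acid), Msln (the surface protein mesothelin) and the unnamed model A730056A06Rik, chosen after their values were seen. Enpp2 had a log2 fold change of -4.42 (adjusted p = 0.00177), Msln of -3.63 (adjusted p = 0.00177) and A730056A06Rik of 7.63 (adjusted p = 0.01). Of genes called in the mean contrast alone, Slc25a10, the mitochondrial dicarboxylate carrier, rose by 1.34 and Mlph, which links pigment granules to myosin, by 0.98. Lpl, the lipoprotein lipase, fell by 1.11, Nrp2 (a semaphorin receptor) fell by 2.19 and Bgn (the proteoglycan biglycan) fell by 3.02 on the same scale. Adcy8, Frmd8, Pcx, Enpp2, Msln and Gvin1 were the 6 genes called in each of the 9 fits that leave out 1 library.

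DESeq2 called 287 genes in the same comparison. The edgeR count was 10, 6 and 7 without sgCtrl 1, 2 or 3, 12 without sgNcor1-1 2, sgNcor1-2 2 or sgNcor1-2 3, and 18 or 19 without the others. With the replicate block edgeR called 525 (184 higher, 341 lower), though the numbers were not taken to pair these libraries.

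**Figure D2:**
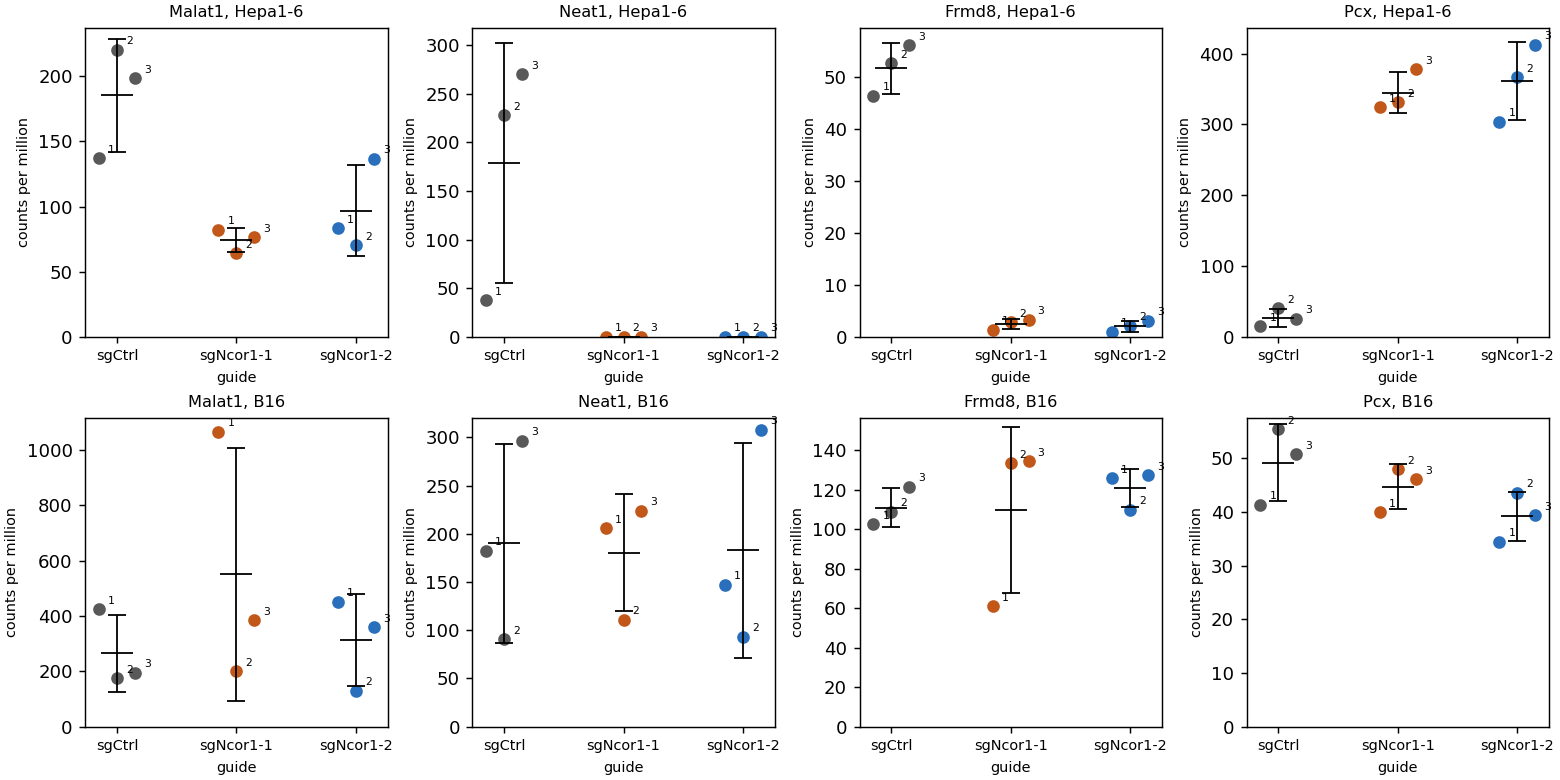
Level in each of the 18 libraries in CPM of Malat1, Neat1, Frmd8 and Pcx, all on chromosome 19, by cell line and guide, with mean ± SD (n = 3). Neat1 is at 0 in the 6 Hepa1-6 knockout libraries and Frmd8 at 0.944 to 3.266 CPM there, while Neat1 stays at 93.3 CPM or more in the B16 knockout libraries.

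Genes of lipid synthesis were higher as lists in Hepa1-6 knockout libraries. The 26 genes of cholesterol biosynthesis all had positive log2 fold changes (median 0.59, adjusted p = 9.4e-11; adjusted p = 0.478 with an estimated correlation). Sqle, an early oxygenase of the pathway, stood at 0.72 (SE 0.17, adjusted p = 0.177). Of 20 genes of fatty acid synthesis 19 were above 0 (median 0.53, adjusted p = 4.02e-08; adjusted p = 0.336 with an estimated correlation). Acaca, which makes malonyl-CoA, stood at 0.79 (SE 0.15), Fasn, the synthase, at 0.81 (SE 0.25) and the desaturase Fads2 at 1.31 (SE 0.32). Adjusted over the list alone, 0 cholesterol genes and 2 fatty acid genes passed, and over all genes tested none of either list did. At an unadjusted p under 0.05, 1383 of all genes tested passed.

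Within numbers 1, 2 and 3, the cholesterol median against the control of the same number was 1.24, 0.44 and 0.04 with sgNcor1-1 and 1.27, 0.53 and 0.07 with sgNcor1-2. The fatty acid medians were 0.85, 0.44 and 0.31 with sgNcor1-1 and 0.83, 0.53 and 0.37 with sgNcor1-2. Targets of the oxysterol receptor LXR were also higher (median 0.41, 13 of 16 above 0, adjusted p = 0.0329; adjusted p = 0.478 with an estimated correlation). Srebf1, the lipogenic regulator, stood at 0.82 (SE 0.19) and Lpcat3, a phospholipid acyltransferase, at 0.83 (SE 0.21), while Lpl was the member called, and it fell. Adjusted over the list alone, 3 LXR targets passed upwards and 1 downwards. PPAR targets did not pass (median 0.22, adjusted p = 0.101).

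Cell cycle lists were higher in Hepa1-6 knockout libraries when all libraries were pooled but not within every number. All 38 genes of G2/M and mitosis were above 0 (median 0.74, adjusted p = 6.35e-10; adjusted p = 0.659 with an estimated correlation). Their median was 1.98, 0.36 and -0.32 within numbers 1, 2 and 3 with sgNcor1-1, and 1.92, 0.34 and -0.29 with sgNcor1-2. Ccnb2, a mitotic cyclin, stood at 1.17 (SE 0.41) and the kinase gene Aurka at 0.82 (SE 0.34). The G1/S and replication genes gave a median of 0.54 (adjusted p = 5.28e-06; adjusted p = 0.659 with an estimated correlation), with 1.06, 0.61 and -0.17 within numbers with sgNcor1-1 and 1.06, 0.24 and -0.33 with sgNcor1-2. Without the libraries numbered 1, neither passed (adjusted p = 0.814 for G2/M and 0.321 for G1/S). Nuclear genes of the respiratory chain had a median of 0.19 with 40 of 42 above 0 (adjusted p = 6.35e-05; adjusted p = 0.659 with an estimated correlation), while mitochondrially encoded mRNAs, a sign of RNA quality, had a median of -0.27 (adjusted p = 0.0433; adjusted p = 0.659 with an estimated correlation) and did not pass with sgNcor1-2 alone (adjusted p = 0.353). Replication-dependent histone mRNAs, another sign of RNA quality, had a median of 0.72 with 10 of 10 above 0 (adjusted p = 0.0694). Across 9785 genes in Hepa1-6 the log2 fold change had a rank correlation of -0.29 with transcript length, against 0 in B16, so shorter transcripts lay higher in Hepa1-6.

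Interferon-stimulated genes, chemokines and cytokines, and collagen and matrix genes were lower as lists in Hepa1-6, and other immune lists did not pass. The median of 55 interferon-stimulated genes was -0.19 (adjusted p = 0.0433; adjusted p = 0.686 with an estimated correlation), with Ifit2 at -1.11 (SE 0.38) and Ddx58, the RIG-I sensor, at -0.51 (SE 0.16). Within numbers the interferon medians were -0.17, -0.47 and 0.03 with sgNcor1-1 and -0.20, -0.37 and 0.02 with sgNcor1-2. Chemokines and cytokines had a median of -0.15 (adjusted p = 0.0436; adjusted p = 0.478 with an estimated correlation), and collagen and matrix genes of -0.18 (adjusted p = 0.021; adjusted p = 0.537 with an estimated correlation). With sgNcor1-2 alone the interferon and chemokine lists did not pass (adjusted p = 0.0661 and 0.112). In the matrix list Bgn was called, and 3 genes passed downwards adjusted over the list alone, among them the collagen crosslinking enzyme Loxl2 at -2.15 (SE 0.37). Genes of MHC class I antigen presentation (adjusted p = 0.216), checkpoint ligands (adjusted p = 0.303), NF-kB targets (adjusted p = 0.0861) and cytosolic nucleic acid sensing (median 0.06, adjusted p = 0.561) did not pass, with B2m at -0.61 (SE 0.20) and Cd274, which encodes PD-L1, at -0.53 (SE 0.37).

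The mismatch repair genes, on which the series title centres, were not called in Hepa1-6 by the main edgeR test over all genes, which leaves changes within the errors given below open. Msh6, which takes part in mismatch recognition, stood at 0.19 (SE 0.18) on the log2 scale, and Pms2, which acts in the next step, at -0.01 (SE 0.27). Msh3 stood at -0.09 (SE 0.36), Pms1 at 0.36 (SE 0.64), Exo1 at 0.83 (SE 0.60) and Pcna at 0.35 (SE 0.26). Their adjusted p-values lay between 0.64 and 0.994. Mlh3, a MutL homologue that also acts in meiosis, was at 6.473 ± 2.86 CPM with sgCtrl, 2.254 ± 0.315 with sgNcor1-1 and 2.595 ± 0.55 with sgNcor1-2 (SD, n = 3 each). Its log2 fold change was -1.42 (SE 0.31, adjusted p = 0.148), and it was the 1 member of 13 that passed adjusted over the list alone. DESeq2 called Mlh3 over all genes (adjusted p = 0.0038). So did edgeR with the replicate block, though the numbers were not taken to pair libraries in this comparison. The core list gave a median of 0.19 (adjusted p = 0.561), and the replication factors used in mismatch repair a median of 0.29 (adjusted p = 0.0614). Within numbers 1, 2 and 3 the core median was 0.6, 0 and 0.03 with sgNcor1-1 and 0.59, -0.26 and -0.12 with sgNcor1-2. The replication factor median was 0.9, 0.16 and -0.03 with sgNcor1-1 and 0.97, 0.15 and -0.12 with sgNcor1-2. These values broadly followed the G1/S medians.

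Taken alone, sgNcor1-1 changed 6 genes in Hepa1-6 (3 higher, 3 lower) and sgNcor1-2 changed 10 (3 higher, 7 lower). The 6 genes called with both guides in the same direction were Adcy8, Pcx and A730056A06Rik, which rose, and Frmd8, Enpp2 and Msln, which fell. Independent lists of these sizes would share 0.000722 genes upwards and 0.00169 downwards. The guides share controls, so all 9 libraries, controls included, were simulated with no change between groups in 10 draws. The simulation held no effect of the replicate number. The correlation of fold changes across genes was 0.92 against 0.51 simulated, the covariance 0.262 against 0.105, and 88.7% of genes had the same sign against 66.8%. The simulated draws gave 0 genes called with both guides. Libraries of the same number of both guides correlated at 0.91, 0.67 and 0.75. The simulation left this out, so it does not show how much of the excess comes from knockout.

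DESeq2 called 94 genes with sgNcor1-1, 112 with sgNcor1-2 and 79 with both, and with the replicate block edgeR called 100 with sgNcor1-2 (40 higher, 60 lower). Leaving out sgCtrl 1, 2 or 3 left 3, 2 and 1 genes called with both guides, leaving out sgNcor1-1 1, 2 or 3 left 5, 2 and 2, and leaving out sgNcor1-2 1, 2 or 3 left 5, 2 and 3.

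Against each other, the guides gave 0 called genes in Hepa1-6 (edgeR), with 9 genes at an unadjusted p under 0.05. DESeq2 and limma-voom also called 0, with 27 and 15 at that level, and edgeR with the replicate block called 0, with 31. Each count is a much smaller share than the 0.05 that unchanged genes would give. The spread was therefore too large for this comparison, and the 0 calls do not show that the guides agree. The gene with the largest difference under the naming rule was COX2, a mitochondrially encoded oxidase subunit, at 11.84 ± 6.63 CPM with sgNcor1-1 and 40.23 ± 20.5 with sgNcor1-2 (log2 difference -1.77, SE 0.80, adjusted p = 1). The noncoding gene Mir100hg stood at -0.67 (SE 0.27) and Arhgef26 at -0.45 (SE 0.25). On the other side Wdr31 stood at 0.44 (SE 0.30), Galnt10 at 0.34 (SE 0.24) and Cenpo at 0.32 (SE 0.25), all with an adjusted p of 1.

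In B16, knockout against control asked the same question in melanoma cells. Pbxip1, which encodes a protein that binds PBX transcription factors, fell from 35.42 ± 11.3 CPM with sgCtrl to 0.395 ± 0.356 with sgNcor1-1 and 0.395 ± 0.0618 with sgNcor1-2 (SD, n = 3 each). It lies on chromosome 3 from 89436675 to 89450952. Its log2 fold change was -6.44 (SE 0.44, adjusted p = 0.000944), and it was the 1 gene that met the rule for naming large changes. No DNA was measured here, so a loss of the gene in the cells of both guides was not tested. The other 3 called genes, chosen after their values were seen, also fell. Ppm1h, a protein phosphatase, fell from 280.3 ± 21 CPM to 109.2 ± 6.27 and 143.2 ± 13.1 (log2 fold change -1.16, SE 0.14, adjusted p = 0.033). Plppr3, of the phospholipid phosphatase-related family, fell from 26.77 ± 10.7 CPM to 4.496 ± 1.17 and 5.228 ± 1.64 (log2 fold change -2.47, SE 0.30, adjusted p = 0.0408). Tenm3, a teneurin adhesion protein, stood at 10.64 ± 3.22 CPM in the controls and at 0 counts in all 6 knockout libraries, at least 44-fold lower against a floor of 3 counts per library (0.242 CPM, adjusted p = 0.033).

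With the replicate number as a block, 48 genes were called in B16, 14 higher and 34 lower. The same fit without sgNcor1-1 1, the library that stood apart, called 339 (157 higher, 182 lower), and without the libraries numbered 1 it called 404 (203 higher, 201 lower). Among them, chosen after their values were seen, Rarb, the retinoic acid receptor beta, rose from 0.9397 ± 0.828 CPM to 6.675 ± 6.07 and 11.29 ± 10.3 (blocked adjusted p = 0.0048, unblocked 1). Kitl, the ligand of the receptor KIT, fell from 20.44 ± 16.1 CPM to 3.391 ± 3.14 and 2.797 ± 2.98 (blocked adjusted p = 0.00546, unblocked 1). Icam1, an adhesion molecule for leukocytes, fell from 36.6 ± 9.29 CPM to 11.29 ± 5.85 and 9.082 ± 1.99 (blocked adjusted p = 0.0233, unblocked 0.111). Angptl4, an inhibitor of lipoprotein lipase, rose from 5.227 ± 1.09 CPM to 36.79 ± 14.5 and 74.43 ± 49.6 (blocked adjusted p = 0.0384, unblocked 0.0671). Each was higher or lower in all 6 pairs of a knockout library with the control of its number. Also lower with the block were Neb (blocked log2 fold change -3.04), Clu (-1.99) and Cav1 (-1.40), and also higher were Slc25a34 (1.73) and Nrp2 (39.79 ± 13.3 CPM with sgCtrl, 81.42 ± 35.4 and 96.25 ± 44.1 with the guides).

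DESeq2 called 48 genes without the block, limma-voom 9, and edgeR without a filter on low counts 17. Without sgNcor1-1 2 edgeR called 3 genes, and without any other single library 1, Pbxip1, while the largest adjusted p on leaving out 1 library was 0.249 for each of Ppm1h, Plppr3 and Tenm3, without sgCtrl 3.

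Interferon-stimulated genes were the list with the smallest p in B16, with 54 of 58 members above 0 (median 0.40, adjusted p = 8.65e-16; adjusted p = 0.402 with an estimated correlation). Ifit3 stood at 1.66 (SE 0.52), with 18.28 ± 5.81 CPM in the controls and 49.97 ± 44.4 and 66.41 ± 17.1 with the guides, Sp100 at 0.87 (SE 0.23) and Oas1g at 0.80 (SE 0.22), none of them called. Over all genes and adjusted over the list alone 0 members passed, against 2 and 16, all upwards, with the replicate block. Within numbers 1, 2 and 3 the median was -0.25, 0.44 and 0.30 with sgNcor1-1 and 0.75, 0.65 and 0.38 with sgNcor1-2. The negative value came from sgNcor1-1 1, the library that stood apart. In that library mitochondrially encoded mRNAs had a median of -1.25 and cytosolic ribosomal protein mRNAs a median of 0.52 against sgCtrl 1, both signs of RNA quality. Genes of MHC class I antigen presentation were also higher (median 0.17, 24 of 25 above 0, adjusted p = 0.000448; adjusted p = 0.36 with an estimated correlation), but not with sgNcor1-2 alone (adjusted p = 0.0663) or without sgNcor1-1 1 (adjusted p = 0.0903). Psmb8, an immunoproteasome subunit, stood at 0.58 (SE 0.25) and B2m at 0.39 (SE 0.25). Checkpoint ligands did not pass (adjusted p = 0.303), nor did chemokines and cytokines (adjusted p = 0.702).

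Targets of the lipid-sensing nuclear receptors were higher in B16 knockout libraries, and these were the 2 lists that passed with an estimated correlation. PPAR targets had a median of 0.20 with 23 of 27 above 0 (adjusted p = 1.64e-06; adjusted p = 0.0339 with an estimated correlation), and LXR targets had a median of 0.34 with 10 of 13 above 0 (adjusted p = 2.51e-05; adjusted p = 0.0458 with an estimated correlation). With both the replicate block and an estimated correlation neither passed (adjusted p = 0.16 and 0.187). Within numbers the PPAR median lay between 0.20 and 0.29 in all 6 pairs and the LXR median between 0.28 and 0.41. Abca1, which exports cholesterol from cells, stood at 1.17 (SE 0.34), with 54.9 ± 10.9 CPM with sgCtrl, 99.25 ± 34.1 with sgNcor1-1 and 153.7 ± 77.7 with sgNcor1-2 (SD, n = 3 each). Mylip, which marks the LDL receptor for breakdown, stood at 0.58 (SE 0.19) and Acadl of fatty acid oxidation at 0.48 (SE 0.15). Adjusted over the list alone, 1 PPAR target (Angptl4) and 0 LXR targets passed, against 3 PPAR targets upwards and 2 downwards, and 5 LXR targets upwards, with the block. Fatty acid synthesis genes had a median of 0.17 (adjusted p = 0.000807; adjusted p = 0.207 with an estimated correlation), and cholesterol biosynthesis did not pass (median 0.02, adjusted p = 0.847).

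Cell cycle lists and 3 of the 4 DNA repair lists were lower in B16, and base and nucleotide excision repair did not pass (median -0.04, adjusted p = 0.354). Of the 38 genes of G2/M and mitosis 1 was above 0 (median -0.24, adjusted p = 1.11e-09; adjusted p = 0.6 with an estimated correlation), and the G1/S and replication genes had a median of -0.23 (adjusted p = 2.51e-05; adjusted p = 0.67 with an estimated correlation). Within numbers the G2/M median was 0, -0.19 and -0.23 with sgNcor1-1 and -0.36, -0.15 and -0.56 with sgNcor1-2, and the G1/S median 0.02, -0.44 and -0.29 with sgNcor1-1 and -0.56, 0.26 and -0.55 with sgNcor1-2. Homologous recombination and Fanconi genes had a median of -0.18 (adjusted p = 2.51e-05; adjusted p = 0.36 with an estimated correlation), with Fancd2 at -0.47 (SE 0.18) and Fanci at -0.41 (SE 0.17). The core mismatch repair list had a median of -0.15 with 2 of 13 above 0 (adjusted p = 0.0417; adjusted p = 0.67 with an estimated correlation). It did not pass with either guide alone (adjusted p = 0.0689 and 0.0838) or without sgNcor1-1 1 (adjusted p = 0.133). The replication factors of mismatch repair also had a median of -0.15 (adjusted p = 0.021; adjusted p = 0.666 with an estimated correlation), and did not pass with sgNcor1-1 alone (adjusted p = 0.422). Within numbers the core median was -0.18, -0.20 and -0.21 with sgNcor1-1 and -0.10, 0.08 and -0.38 with sgNcor1-2. The replication factor median was 0.18, -0.27 and -0.19 with sgNcor1-1 and -0.29, 0 and -0.39 with sgNcor1-2, which broadly followed the G1/S medians.

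None of the 7 mismatch repair genes named here was called in B16 (edgeR, adjusted p = 1 for each). On the log2 scale Msh3 stood at -0.21 (SE 0.33), Msh6 at -0.20 (SE 0.13) and Mlh3 at -0.28 (SE 0.74). Pms1 stood at -0.32 (SE 0.22), Pms2 at -0.15 (SE 0.19), Exo1 at -0.25 (SE 0.56) and Pcna at -0.12 (SE 0.36). Of all genes tested in B16, 291 had an unadjusted p under 0.05, and 994 with the replicate block (edgeR). The 291 are a smaller share than the 0.05 that unchanged genes would give, so the spread in that fit may be too large. The errors above come from that fit, in which differences between numbers count as error. With the block, 0 members of the core mismatch repair list were called higher and 0 lower.

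**Figure D3:**
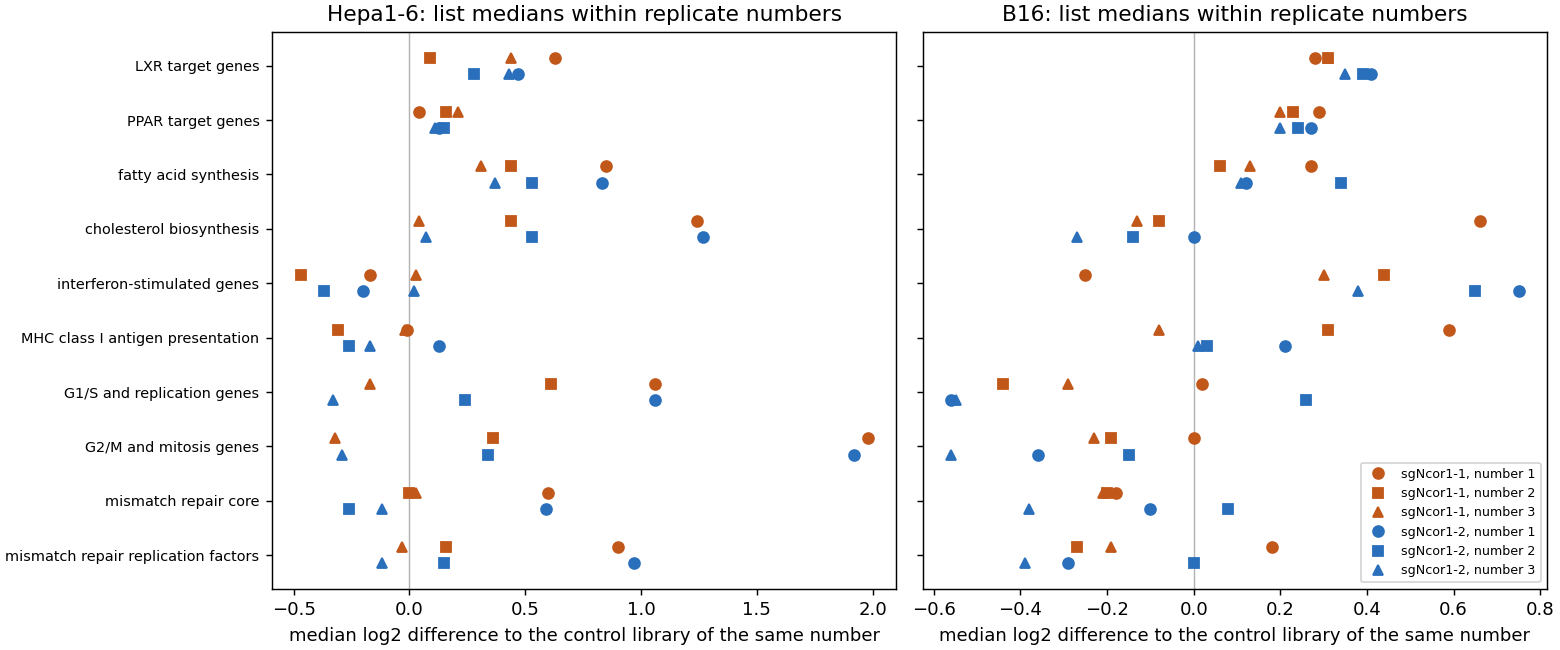
Median log2 difference between each knockout library and the control library of the same number for 10 gene lists in Hepa1-6 and B16, with colour for the guide and shape for the number. The 12 LXR medians lie between 0.09 and 0.63, while the Hepa1-6 G2/M medians run from -0.32 to 1.98.

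Each B16 guide alone gave 1 called gene, Pbxip1, which fell with both (adjusted p = 0.0151 with sgNcor1-1 and 0.013 with sgNcor1-2). Independent lists of that size would share 8.1e-05 genes, and simulated unchanged groups shared 0. With the replicate block 11 genes were called with sgNcor1-1 and 22 with sgNcor1-2, of which 9 fell and 1 rose with both, where independent lists would share 0.0124 and 0.00081. The correlation of fold changes across genes was 0.69 against 0.50 simulated, the covariance 0.151 against 0.113, and 59.9% of genes had the same sign against 66.6%. With 3 controls per line these could not be split into parts of at least 2 libraries, so part of any excess in either line may come from the shared controls. Part may also come from the replicate numbers, which the simulation left out.

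DESeq2 called 32 genes with sgNcor1-1 and 31 with sgNcor1-2, 23 of them with both. The Pbxip1 call with both guides was kept only without sgCtrl 2, sgNcor1-1 1 or sgNcor1-1 2, and leaving out any of the other 6 libraries left 0 genes.

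Between the guides in B16 0 genes were called (edgeR), with 46 at an unadjusted p under 0.05. DESeq2 and limma-voom called 0, with 112 and 36 at that level, and edgeR with the block called 0, with 662. Without the block these shares are also far under 0.05, so the 0 calls there do not show that the guides agree. ATP6, a mitochondrially encoded subunit of ATP synthase, differed most under the naming rule, at 11.61 ± 2.29 CPM with sgNcor1-1 and 44.51 ± 24.9 with sgNcor1-2 (log2 difference -1.94, SE 0.43, adjusted p = 1). Apol9b stood at -1.17 (SE 0.38) and Card14 at -0.88 (SE 0.34). On the other side Lgals7 stood at 5.196 CPM with sgNcor1-1 and 2.095 with sgNcor1-2, and the log2 difference was 0.89 for Nxt1 (SE 0.41) and 0.75 for Nop10 (SE 0.30), all with an adjusted p of 1. Against control, ribosomal proteins were higher with sgNcor1-1 (adjusted p = 0.0309) and lower with sgNcor1-2 (adjusted p = 6.75e-11), and so were respiratory chain genes (adjusted p = 0.000838 and 0.000474), by the preset correlation alone and with no test of lists between the guides. For both guides together the lists had adjusted p = 0.934 and 0.954 with an estimated correlation, which was not run for each guide. Within numbers 1, 2 and 3 the ribosomal median was 0.52, -0.06 and -0.14 with sgNcor1-1 and -0.17, -0.32 and -0.17 with sgNcor1-2, so the high value came from sgNcor1-1 1, the library that stood apart. The respiratory chain median was 0.48, 0.02 and -0.08 with sgNcor1-1 and -0.14, -0.18 and -0.08 with sgNcor1-2. Without sgNcor1-1 1 ribosomal proteins were lower with knockout by the preset correlation (adjusted p = 5.83e-08) and respiratory chain genes did not pass (adjusted p = 0.124).

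The last comparison asked whether the knockout effect differed between the lines, by the test of the difference itself. Pcx rose in Hepa1-6 and stood at 49.18 ± 7.17, 44.69 ± 4.19 and 39.15 ± 4.57 CPM in B16, a log2 difference of 3.96 (SE 0.34, adjusted p = 2.39e-05). Pbxip1 fell in B16 and stood at 22.8 ± 6.01, 18.96 ± 9.65 and 18.4 ± 6.54 CPM in Hepa1-6, a difference of 6.16 (SE 0.61, adjusted p = 5.84e-05). Neat1 was absent from the Hepa1-6 knockout counts and stood at 190 ± 103, 180.4 ± 60.7 and 182.8 ± 112 CPM in B16 (adjusted p = 0.00017). In all 25 genes differed, 10 towards a higher effect in Hepa1-6 and 15 towards a lower one. DESeq2 gave 107, and without the B16 library sgCtrl 3 the edgeR count was 15.

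Without the block no gene was called in both lines (edgeR), where independent lists of these sizes would share 0.0011 to 0.00404 genes in the directions that both hold calls. With the replicate block in both lines 2 genes, Nrp2 and Sv2a, were lower in Hepa1-6 and higher in B16 (0.207 expected), and 1, Zfp941, was lower in both (0.596 expected). In Hepa1-6 the numbers were not taken to pair knockout with control libraries. The correlation of log2 fold changes between the lines across 10878 genes was -0.06, and genes are not independent replicates. The cell cycle lists differed most, with adjusted p = 5.14e-16 for G2/M (adjusted p = 0.422 with an estimated correlation) and 1.12e-08 for G1/S (adjusted p = 0.438 with an estimated correlation), higher in Hepa1-6. In Hepa1-6 neither passed without the libraries numbered 1 (adjusted p = 0.814 and 0.321), and in number 3 the G2/M medians were -0.32 and -0.29 in Hepa1-6 and -0.23 and -0.56 in B16. Interferon-stimulated genes were lower in Hepa1-6 than in B16 by the effect of knockout (adjusted p = 1.87e-08; adjusted p = 0.422 with an estimated correlation), and so were MHC class I genes (adjusted p = 0.006; adjusted p = 0.422 with an estimated correlation). The list tests took no account of chromosomes. Genes on chromosome 17 had a median of -0.13 in Hepa1-6 and 0.03 in B16, and whether this shift moved a list was not tested. The replication factors of mismatch repair differed (adjusted p = 0.00527; adjusted p = 0.422 with an estimated correlation) and the core list did not pass (adjusted p = 0.0999). Within numbers the replication factor medians broadly followed the G1/S medians in both lines. Their difference was therefore not told apart from that of the cell cycle lists. The difference did not pass for LXR targets (adjusted p = 0.678) or PPAR targets (adjusted p = 0.357).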

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

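The tests on Neat1 and Frmd8 below were chosen after the result was seen. Each result here was picked out because the effect of knockout differed between Hepa1-6 and B16 by the test of the difference itself.

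Pcx differed by 3.96 on the log2 scale (SE 0.34, adjusted p = 2.39e-05). Pbxip1 differed by 6.16 (SE 0.61, adjusted p = 5.84e-05). Zfp941, a zinc finger gene, differed by 4.8 (SE 0.76, adjusted p = 0.00806), with 20.58 ± 2.89, 12.42 ± 3.66 and 12.4 ± 3.23 CPM in Hepa1-6 and 1.115 ± 0.607, 0.02 ± 0.0346 and 0.01833 ± 0.0318 in B16 (SD, n = 3 each, in the order sgCtrl, sgNcor1-1, sgNcor1-2). Repin1, a zinc finger gene, differed by -5.12 (SE 0.48, adjusted p = 3.57e-05), with 3.938 ± 0.739, 0.1477 ± 0.0415 and 0.08567 ± 0.0795 CPM in Hepa1-6 and 52.49 ± 4.04, 66.21 ± 24.7 and 49.51 ± 9.74 in B16. Gstt2, a glutathione transferase, differed by -6.01 (SE 0.615, adjusted p = 5.84e-05), with 1.323 ± 0.258, 0.06033 ± 0.0573 and 0.01033 ± 0.0179 CPM in Hepa1-6 and 10.42 ± 1.52, 17.65 ± 2.36 and 17.01 ± 3.52 in B16. Neat1 differed by -14.81 (adjusted p = 0.00017), a size that depends on the prior count since it had 0 counts in the Hepa1-6 knockout libraries.

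Among gene lists, the effect was higher in Hepa1-6 for G2/M and mitosis genes (adjusted p = 5.14e-16; adjusted p = 0.422 with an estimated correlation) and G1/S and replication genes (adjusted p = 1.12e-08; adjusted p = 0.438 with an estimated correlation). It was higher there for cholesterol biosynthesis (adjusted p = 8.11e-07; adjusted p = 0.422 with an estimated correlation) and fatty acid synthesis (adjusted p = 0.0219; adjusted p = 0.422 with an estimated correlation). It was also higher for homologous recombination and Fanconi genes (adjusted p = 0.000356; adjusted p = 0.446 with an estimated correlation), and for mismatch repair replication factors (adjusted p = 0.00527; adjusted p = 0.422 with an estimated correlation). The nuclear-encoded respiratory chain differed the same way (adjusted p = 0.00314; adjusted p = 0.548 with an estimated correlation). In Hepa1-6 alone, without the libraries numbered 1, which stood apart, the list did not pass for G2/M (adjusted p = 0.814), G1/S (0.321), homologous recombination and Fanconi genes (0.711) or mismatch repair replication factors (0.835). The replication factor medians broadly followed those of G1/S in both lines. The effect was lower in Hepa1-6 for interferon-stimulated genes (adjusted p = 1.87e-08; adjusted p = 0.422 with an estimated correlation), MHC class I antigen presentation (adjusted p = 0.006; adjusted p = 0.422 with an estimated correlation) and collagen and matrix genes (adjusted p = 0.0181; adjusted p = 0.422 with an estimated correlation). Whether a shift of a chromosome, such as 17 in Hepa1-6, moved any of these lists was not tested. Of 40 splits, the real one and random regroupings of the libraries within each line, 2 gave as many genes as the real one, the real one included (27 genes in the fit used for splits, which pools the 2 guides of a line, and highest other 812), so chance was not excluded for a count of this kind. These regroupings ignored the replicate number, and none was run with the replicate block, which called 236 genes.

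Neat1 and Frmd8, neighbours on chromosome 19, were near 0 in the 6 Hepa1-6 knockout libraries. Depth cannot account for this, since 660 Neat1 counts were expected in the shallowest knockout library at the lowest control level and 0 were found. Nor can the counting of the gene, since the lowest Neat1 level in the 6 B16 knockout libraries was 93.3 CPM. A loss at this place in the cells of both guides could account for it and cannot be settled without DNA: Frmd8 stood at 4.35% of its control mean, with Malat1 on one side at 46.2% and Dpf2 on the other at 98.1%. An effect of Ncor1 itself has the same groups, so the design does not separate the 2.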

How the results depend on the processing

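Most values of named genes kept their side of the threshold: of 2986 pairs of a gene and a setting, 1554 in Hepa1-6 and 1105 in B16 did, 60 and 44 passed only in the alternative, 185 and 38 no longer passed, and no called value changed sign. Of those on the same side, 33 that were called in neither changed sign. The main test called 25 of the 86 genes counted here in Hepa1-6 and 4 of the 54 in B16, so most values had no call to lose. Of the called genes, 6 in Hepa1-6 and 1 in B16 were called in each fit that leaves out 1 library. The cause was not tested unless stated. Depth limits genes near 0 counts. The counts below are in the order knockout, sgNcor1-1, sgNcor1-2, both guides.

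In Hepa1-6 (25, 6, 10 and 6 genes) DESeq2 gave 287, 94, 112 and 79. The replicate block gave 525, 81, 100 and 65, and with DESeq2 1215, 625, 703 and 492 (25 between guides). Leaving out the libraries numbered 1 gave 12 for sgNcor1-1 and 11 for both, and with the replicate block 75, 24, 24 and 18. Leaving out those numbered 2 gave 0, 0, 0 and 0, and those numbered 3 gave 0, 0, 0 and 0, with fewer libraries. No filter on low counts gave 11 for sgNcor1-1 and 11 for both, only the 6 libraries compared gave 10 for sgNcor1-1 and 5 for sgNcor1-2, and one knockout group 44. Leaving out 1 library gave 6 to 19, 1 to 11, 1 to 12 and 1 to 5.

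In B16 (4, 1, 1 and 1 genes) DESeq2 gave 48, 32, 31 and 23, limma-voom 9, 3, 2 and 2, and no filter on low counts 17, 2, 3 and 2. The replicate block gave 48, 11, 22 and 10, with DESeq2 201, 147, 154 and 87 (12 between guides), without the libraries numbered 1 404, 167, 291 and 131, and without sgNcor1-1 1 339, 61, 266 and 57. Leaving out the libraries numbered 1 gave 0, 0, 0 and 0, those numbered 2 1, 0, 0 and 0, and those numbered 3 0, 0, 0 and 0. Only the 6 libraries compared gave 0 for sgNcor1-1 and 0 for both, and one knockout group 11. Leaving out 1 library gave 1 to 3, 0 to 1, 0 to 1 and 0 to 1.

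Between the lines (25 genes) DESeq2 gave 107, the replicate block 236, and leaving out 1 library 15 to 30. Of gene lists, 10 passed in Hepa1-6, with 0 by an estimated correlation, 0 with the replicate block and an estimated correlation, 17 without the libraries numbered 1, 0 by fry and 0 by fry with the replicate block. In B16 10 passed, with 2 by an estimated correlation, 0 with the replicate block as well, 1 by fry and 2 by fry with the replicate block. The replicate block changed no B16 list call by camera with the preset correlation, and by fry it brought in fatty acid synthesis (adjusted p = 0.0178, against 0.333 without it). Between the lines 10 passed, with 0 by an estimated correlation. In Hepa1-6 8 of 9 libraries correlated best with a library of their own number, and in B16 9 of 9. With the replicate block Ncor1 in Hepa1-6 had an adjusted p of 0.0453 and Mlh3 of 0.0357.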

Other observations

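The tests of splits, of the stretch and copies of chromosome 6 and of LXR medians over pairs below were chosen after the result was seen.

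Hypoxia and glycolysis genes, hepatocyte genes and markers of other cells were measured but did not pass as lists in the main test in Hepa1-6. Pdk1, the kinase that closes pyruvate dehydrogenase, stood at 38.77 ± 7.03 CPM with sgCtrl, 79.64 ± 11.7 with sgNcor1-1 and 83.89 ± 8.58 with sgNcor1-2 (SD, n = 3 each; log2 fold change 1.08, SE 0.18, adjusted p = 0.059). It was the 1 gene of its list that passed adjusted over the list alone (list median 0.34, adjusted p = 0.0503). The hypoxia and glycolysis list passed with sgNcor1-1 alone (adjusted p = 0.0407, camera), and did not pass with an estimated correlation (adjusted p = 0.776, camera). Afp, the fetal liver protein alpha-fetoprotein, stood at 123.5 ± 22.2, 255.5 ± 106 and 280.1 ± 104 CPM (adjusted p = 0.226; hepatocyte list adjusted p = 0.745). Pdgfra, a growth factor receptor of fibroblasts, stood at 19.56 ± 1.59, 8.987 ± 2.34 and 8.889 ± 1.48 CPM (adjusted p = 0.115), in a list of fibroblast and endothelial markers with 5 measured members (adjusted p = 0.0694). Of leukocyte markers 4 were measured in Hepa1-6 and 2 in B16, too few to test.

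Melanocyte identity genes did not pass in B16 (median 0.18, adjusted p = 0.503), with Sox10, a neural crest regulator, at 303.5 ± 65.1, 357.5 ± 77.9 and 429.7 ± 112 CPM. Targets of p53 did not pass in either line (adjusted p = 0.168 in Hepa1-6 and 0.652 in B16). Median, mean and test differed in sign for some lists that did not pass. In Hepa1-6 these were thyroid hormone and retinoid targets (0.04, -0.06, up), NRF2 genes (0.03, -0.03, down) and immediate early genes (0.04, -0.05, down). In B16 they were NF-kB targets (0.01, -0.04, down), thyroid hormone and retinoid targets (-0.02, 0.44, up), fibroblast and endothelial markers (0.09, -0.11, down) and immediate early genes (0.04, -0.07, down).

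Genes on chromosome 6 had a median log2 fold change of -0.18 in B16 (513 genes). Trends on GC content, transcript length and expression did not remove it (-0.196 after them), and it was no matter of a few genes, since 85.2% lay below the median of all genes. Nor was it 1 stretch, since 98.3% of windows of 31 genes lay under -0.1. Fewer copies of chromosome 6 in the cells of both guides could account for it and cannot be settled without DNA (smallest shift of 6 pairs -0.17). Other chromosomes had low medians too: X in B16 at -0.16 (303 genes, pairs -0.38 to -0.01) and 17 in Hepa1-6 at -0.13 (491 genes), while 6 in Hepa1-6 stood at 0.06 (465 genes).

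A hypothesis was that Ncor1 represses LXR target genes in both lines. The median was above 0 in 12 of 12 pairs of a knockout library with the control of its number, which it needs, but PPAR targets and fatty acid synthesis genes were also above 0 in all 12, so this is not particular to LXR. Of 10000 random lists of the same size and expression none did as well (share 1e-04), but the list was picked for these pairs and random genes are not regulated together, so neither value decides. Genes shared with fatty acid synthesis may contribute: without them the median was above 0 in 10 of 12 pairs, with -0.20 and -0.03 in the Hepa1-6 libraries numbered 2, which leaves this open. The pairs of a number share a control library.

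Pbxip1 and Tenm3 in B16, like Neat1 and Frmd8 in Hepa1-6, were near 0 with both guides. Without DNA, a loss in the cells of both guides was not told apart from an effect of Ncor1 for these genes either.

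Libraries were regrouped to see how often as many genes or lists were called, the real grouping included. These fits pool the 2 guides into 1 knockout group, so their real counts differ from those of the comparisons, 25 and 4 genes without the block and 525 and 48 with it. For knockout against control 3 of 84 splits in Hepa1-6 (44 genes, highest other 4654) and 4 of 84 in B16 (11 genes, highest other 1756) gave as many genes, a share under 0.05. The splits with most calls set the libraries of 1 number against the rest, so they follow the structure of the samples. The splits are therefore not interchangeable, and these shares do not exclude chance. With the replicate block 1 of 27 gave as many in each line (1109 genes in Hepa1-6 and 43 in B16, highest other 1 in each), the lowest share that 27 splits can give. For the pooled fit in B16, where the numbers were taken to pair the libraries, this argues against chance. In Hepa1-6 the numbers were not taken to pair knockout with control, so it does not decide there.

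For lists chance was not excluded, with 49 of 84 splits in Hepa1-6 (10 lists, highest other 17) and 43 of 84 in B16 (10 lists, highest other 18). With the block, 10 of 27 (14 lists, highest other 17) and 18 of 27 (9 lists, highest other 17) did. Contrasts of single guides and between guides had 10 splits each, too few for a share under 0.05.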
